A study of Homo sapiens with 12 samples.

How the data were processed

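RNA was measured by bulk sequencing in 12 libraries of human organoids at day 86 of differentiation from H9, an established human embryonic stem cell line. Per the labels, total RNA was extracted with a FastPure kit and libraries were made with a TruSeq RNA kit. The sample titles combine a prefix, M or N, with a suffix, ctrl or de, and a number from 1 to 3, which gives 4 groups of 3 libraries called M_ctrl, M_de, N_ctrl and N_de here. The labels do not define M, N or de, and no meaning was assumed for them. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

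The deposited table holds estimated counts per gene, that is reads assigned to each gene by a model, with 13.3% to 16.4% of the values of a library not whole. STAR 2.7.10a, Salmon 1.10.1 and the genome build GRCh38 are named per the submitters' processing notes, with no role or order. The annotation release and any filter the authors applied are not given in the sources used here. Nor is it stated whether the counting used strand, so overlapping genes on opposite strands, pseudogenes and close paralogs may share reads and are called uncertain where named. Gene positions and types came from GENCODE release 29 on GRCh38, which may not be the release the authors used. It matched 18534 of the 19318 genes tested.

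The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 19318 of the 62754 genes of the table. Libraries were scaled by TMM factors. CPM, the counts scaled to a common library total, and log2(CPM + 1) were computed with those factors and given as mean ± SD over 3 libraries. edgeR 4.0.16 in R 4.3.3 fitted 1 quasi-likelihood model with a mean per group to all 12 libraries, which left 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 4 comparisons were M_ctrl against N_ctrl, M_de against M_ctrl, N_de against N_ctrl, and the difference between the latter pair, which is the interaction of prefix and suffix. The differences called an effect of de below are those of de from ctrl libraries, and no treatment is assumed. Each log2 fold change is given with its standard error (SE), and each adjusted p for a gene is from edgeR's quasi-likelihood test. The common biological coefficient of variation was 22.9%.

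Gene sets were 47 lists of markers and pathway members, with all 1087 entries found in the table and 46 lists holding at least 3 tested genes. They were tested by camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 46 lists. Camera with an estimated correlation and fry were run beside it. Members of a list were counted both by the p adjusted over all genes and by the p adjusted over the list alone. List levels per library are means of log2(CPM + 1) over tested members. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so levels are described and not tested.

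The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the genes named per comparison were up to 8 higher and 8 lower genes with the largest fold changes among those called, with a mean of at least 5 CPM in the higher group, an official symbol and every library of a group above every library of the other. To these were added up to 4 members per called list and up to 2 per other list described, those with the smallest p in the list's direction. For the interaction the condition on single libraries was left out, and where fewer than 5 genes qualified the 5 with the smallest p were named. Many genes met the rule, and those written about are a subset picked after their values were seen. A further gene that met the rule is not reported here.

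The steps were tested on simulated counts drawn from the means and sizes of the real libraries. Of 19318 genes, 59, 71 and 70 were changed 1.5-fold, 2-fold and 4-fold. In M_de against M_ctrl, 5.09%, 36.6% and 94.3% of these were called. For N_de against N_ctrl the shares were 10.2%, 42.3% and 91.4%, and for M_ctrl against N_ctrl they were 1.69%, 43.7% and 87.1%. The interaction recovered 0%, 9.86% and 70% of them. Between 2 and 7 unchanged genes were called per comparison. Recovery at a given adjusted p depends on how many genes change, and M_de against M_ctrl and M_ctrl against N_ctrl had far more calls. The simulated shares therefore do not measure what was missed in the real data. Precision in the real data was set by the spread between libraries, with a median SE on the log2 scale of 0.24 for either comparison of de with ctrl, 0.25 for M_ctrl against N_ctrl and 0.34 for the interaction.

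Alternatives planned in advance were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma voom, no filter on low counts, minimums of 1 or 10 CPM in 3 libraries, only the compared groups in the fit, a robust fit, a log2 fold threshold of 1, the replicate number as a block, another pseudocount or no TMM for list levels, and leaving out each library. A correction for transcript length and GC content was added after seeing the data. It took out of each library a smooth trend over both (splines with 5 degrees of freedom) as an offset in the same model. The trend included a constant per library, so the correction also changed the scaling between libraries. Both values were known for 95.9% of the tested genes. On simulated counts of unchanged genes given the trend that the correction itself fits, it moved the rank correlation of fold change with length from -0.65 to -0.03. This checks the step and does not show whether real differences that follow length are spared. The same correction without N_ctrl replicate 2, and a block for the 2 runs of library names in the table's column order, were also added after seeing the data. No library was left out of the main comparisons. Figures were drawn with matplotlib 3.10.9.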

Results

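Bulk RNA sequencing was carried out on human neuromusculoskeletal organoids, three-dimensional cultures meant to hold nerve, muscle and skeletal tissue together, at day 86. Each of the groups M_ctrl, M_de, N_ctrl and N_de held 3 libraries. The M_ctrl libraries had totals of 18804030, 25831036 and 18009556 estimated counts for replicates 1, 2 and 3, and the M_de libraries had 21457519, 21292768 and 21695278. The N_ctrl libraries had 19333551, 23355319 and 18495039, and the N_de libraries had 21464006, 20169958 and 17824540. The correlation of log2 CPM across genes between libraries of a group was 0.948 to 0.986, and no pair of libraries differed by as little as sampling noise, with a chi-square per gene of 7.64 to 93.4. The first principal component held 59.6% of the variance and separated M from N libraries, and the component after it held 10.5%. On that later component M_ctrl replicate 1 (58.9) and N_ctrl replicates 1 and 3 (48.1 and 41.4) lay highest. N_ctrl replicate 2 lay at -14.1, nearer to the N_de libraries at -28.1 to -21.9. M_ctrl replicates 2 and 3 lay at 13.6 and -17.3, and the M_de libraries at -25.9 to -11.9.

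Most sarcomere and fibroblast matrix genes were called higher in M_ctrl than in N_ctrl, and most general neuronal and ciliated cell genes were called lower. This comparison asks which tissues' genes the libraries labelled ctrl held under each prefix. MYBPC1, a myosin-binding protein of the sarcomere, stood at 3650 ± 111 CPM in M_ctrl and 409 ± 57.9 CPM in N_ctrl (SD, n = 3), a log2 fold change of 3.16 ± 0.16 (SE) with an adjusted p of 2.43e-07 in edgeR. All 46 tested sarcomere genes were called higher in M_ctrl, also when adjusted over the list alone, with a median log2 fold change of 2.75. Their camera adjusted p was 1.12e-46 with the preset correlation and 0.0641 with an estimated correlation. All 14 fast fibre genes were higher by either adjustment, with a median of 3.5 and an adjusted p of 3.57e-18 (adjusted p = 0.0706 with an estimated correlation). All 12 slow fibre genes were higher too by either adjustment, with a median of 2.64 and an adjusted p of 1.01e-10 (adjusted p = 0.114 with an estimated correlation). Fetal myosin MYH8 averaged 8330 ± 314 CPM against 989 ± 204 CPM, and embryonic myosin MYH3 averaged 18200 ± 3600 CPM against 5490 ± 1730 CPM. Slow myosin MYH7 differed by 3.02 ± 0.28 and the fast fibre gene ACTN3 by 4.29 ± 0.29 on the log2 scale. The largest differences included PERM1, a regulator of oxidative genes in muscle, at 5.62 ± 0.33, and TMOD4, a thin filament capping protein, at 5.25 ± 0.40.

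Of 24 tested myogenic regulators 21 were higher in M_ctrl, with a median log2 fold change of 1.85 and a camera adjusted p of 1.44e-11 (adjusted p = 0.0899 with an estimated correlation). Of 17 postsynaptic genes of the neuromuscular junction 10 were higher and 3 lower, with a median of 0.99 and an adjusted p of 0.000891 (adjusted p = 0.221 with an estimated correlation). The acetylcholine receptor genes CHRNA1 and CHRNG differed by 2.93 ± 0.22 and 2.94 ± 0.23 on the log2 scale. Genes that denervation and atrophy raise in muscle were the 1 list that held with an estimated correlation: 17 of 22 were higher and 1 lower, with a median of 1.67, an adjusted p of 1.03e-10 with the preset correlation and an adjusted p of 0.0196 with the estimated correlation. That list shares CHRNA1, CHRNG and other muscle genes with the lists above. Adjusted over the list alone, the counts were the same for these 3 lists.

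Among connective tissue genes, 30 of 37 fibroblast matrix genes were higher and 2 lower in M_ctrl (31 and 2 adjusted over the list alone), with a median log2 fold change of 1.80 and a camera adjusted p of 7.01e-16 (adjusted p = 0.0942 with an estimated correlation). COL1A1 and COL3A1, the main fibrillar collagen genes, stood at 6980 ± 483 and 13200 ± 919 CPM in M_ctrl against 587 ± 252 and 1870 ± 420 CPM in N_ctrl. PRRX1, a transcription factor of limb mesenchyme, differed by 2.89 ± 0.15 on the log2 scale. Tendon and ligament genes were higher in 13 of 18 and lower in 2 (13 and 3 adjusted over the list alone), with a median of 2.53 and an adjusted p of 1.33e-09 (adjusted p = 0.0706 with an estimated correlation). Cartilage genes were more mixed, with 14 of 30 higher and 7 lower (14 and 8 adjusted over the list alone), a median of 0.88 and an adjusted p of 0.0472 (adjusted p = 0.302 with an estimated correlation), a call that ended without M_ctrl replicate 1 or N_ctrl replicate 2 or 3. COL9A3 and COL11A1, which encode cartilage collagen chains, were among those higher, by 2.66 ± 0.32 and 2.20 ± 0.17. Of 16 osteoblast genes 8 were higher and 2 lower by either adjustment, with a median of 0.59 and an adjusted p of 0.0266 (adjusted p = 0.313 with an estimated correlation), and after correction for length and GC content the median was 0.92. The osteoblast call ended without M_ctrl replicate 1, with an adjusted p of 0.0606, and the median was 0.98 without N_ctrl replicate 1.

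Most general neuronal, synaptic and motor neuron genes were called lower in M_ctrl than in N_ctrl. Of 26 general neuronal genes 23 were called lower and 1 higher by either adjustment, with a median log2 fold change of -1.82 and a camera adjusted p of 4.72e-08 (adjusted p = 0.302 with an estimated correlation). Of 35 synaptic genes 29 were lower and 1 higher by either adjustment, with a median of -1.65 and an adjusted p of 1.21e-08 (adjusted p = 0.302 with an estimated correlation). NEFL, the neurofilament light chain gene, stood at 84.4 ± 19.7 CPM in M_ctrl and 987 ± 370 CPM in N_ctrl, and the synaptic vesicle fusion gene SNAP25 at 20.7 ± 6.71 and 90.2 ± 18.4 CPM. Of 16 motor neuron genes 13 were lower (15 adjusted over the list alone), with a median of -2.45 and an adjusted p of 2.53e-08 (adjusted p = 0.0831 with an estimated correlation). CHAT and SLC5A7, which serve acetylcholine synthesis and choline uptake, had log2 fold changes of -3.96 ± 0.31 and -3.58 ± 0.34. TPH2, the enzyme of serotonin synthesis in neurons, had -4.50 ± 0.32. Spinal interneuron genes were not called as a list, with 5 of 18 higher and 7 lower by either adjustment, a median of -0.19 and an adjusted p of 0.455.

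Most neural progenitor, astrocyte and ciliated cell genes were called lower in M_ctrl as well. Of 27 neural progenitor genes 15 were lower and 4 higher (17 and 4 adjusted over the list alone), with a median log2 fold change of -0.98 and a camera adjusted p of 0.000823 (adjusted p = 0.302 with an estimated correlation). The floor plate genes SHH, FOXA2 and CORIN had log2 fold changes of -2.87 ± 0.20, -3.63 ± 0.43 and -5.26 ± 0.53. Of 20 astrocyte genes 13 were lower and 1 higher (15 and 1 adjusted over the list alone), with a median of -1.01 and an adjusted p of 0.000199 (adjusted p = 0.114 with an estimated correlation). Schwann cell and oligodendrocyte genes were not called as a list, with 6 of 20 higher and 10 lower (6 and 12 adjusted over the list alone) and an adjusted p of 0.516. Of 17 genes of ciliated ependymal and choroid plexus cells 15 were lower and 1 higher by either adjustment, with a median of -2.65 and an adjusted p of 2.17e-06 (adjusted p = 0.302 with an estimated correlation). The ciliary gene RSPH1 stood at 3.76 ± 0.553 CPM in M_ctrl and 33.4 ± 16.7 CPM in N_ctrl. TTR, a choroid plexus gene, had 1 count over the M_ctrl libraries and 1405 over the N_ctrl libraries, a ratio of 1150 with a counting interval of 206 to 45500. That interval covers the sampling of reads in the summed counts and leaves out the spread between libraries. Of 23 HOX genes of cervical and brachial segments 15 were lower and 2 higher by either adjustment, with a median of -0.91 and an adjusted p of 0.000113 (adjusted p = 0.384 with an estimated correlation), and HOXB8 had -2.42 ± 0.29.

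All 46 ribosomal protein genes and 48 of 50 nuclear genes of the respiratory chain were called higher in M_ctrl by either adjustment, with median log2 fold changes of 1.91 and 1.64. Their camera adjusted p values were 2.39e-16 and 6.22e-18 with the preset correlation, and either adjusted p was 0.302 with an estimated correlation. Of 34 hypoxia and glycolysis genes 20 were higher and 3 lower (21 and 3 adjusted over the list alone), with a median of 0.94 and an adjusted p of 2.11e-08 (adjusted p = 0.274 with an estimated correlation). LDHA and CA9 differed by 2.45 ± 0.17 and 4.15 ± 0.38. Of 13 mitochondrially encoded genes 12 were higher by either adjustment, with a median of 1.28 and an adjusted p of 0.000305 (adjusted p = 0.391 with an estimated correlation), but after correction for length and GC content the median was 0.56 and the adjusted p 0.0775. The ribosomal and respiratory lists are rich in short transcripts, and coding genes with transcripts of up to 1000 bases had a median log2 fold change of 1.02 against -0.25 for those over 6000 bases. In M libraries the 20 most abundant genes took 12.7% to 16.7% of counts, against 7.15% to 8.68% in N libraries.

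In total 4583 genes were higher and 4713 lower in M_ctrl among the 19318 tested, and 2734 and 3044 of these differed at least 2-fold. Of the 46 lists 21 were higher and 7 lower with the preset correlation, and 1 of these 28 was called with an estimated correlation. Fry called 35 of the 46 lists. Smooth muscle and pericyte genes were higher in 8 of 14 and lower in 1 by either adjustment, with a median of 0.97 and an adjusted p of 0.00066 (adjusted p = 0.154 with an estimated correlation). Matrix degradation genes were higher in 10 of 16 and lower in 2 (11 and 2 adjusted over the list alone), with a median of 0.71 and an adjusted p of 0.0133 (adjusted p = 0.0942 with an estimated correlation). NF-kB inflammation genes were higher in 13 of 24 by either adjustment, with a median of 0.75 and an adjusted p of 0.00325 (adjusted p = 0.307 with an estimated correlation).

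**Figure D1:**
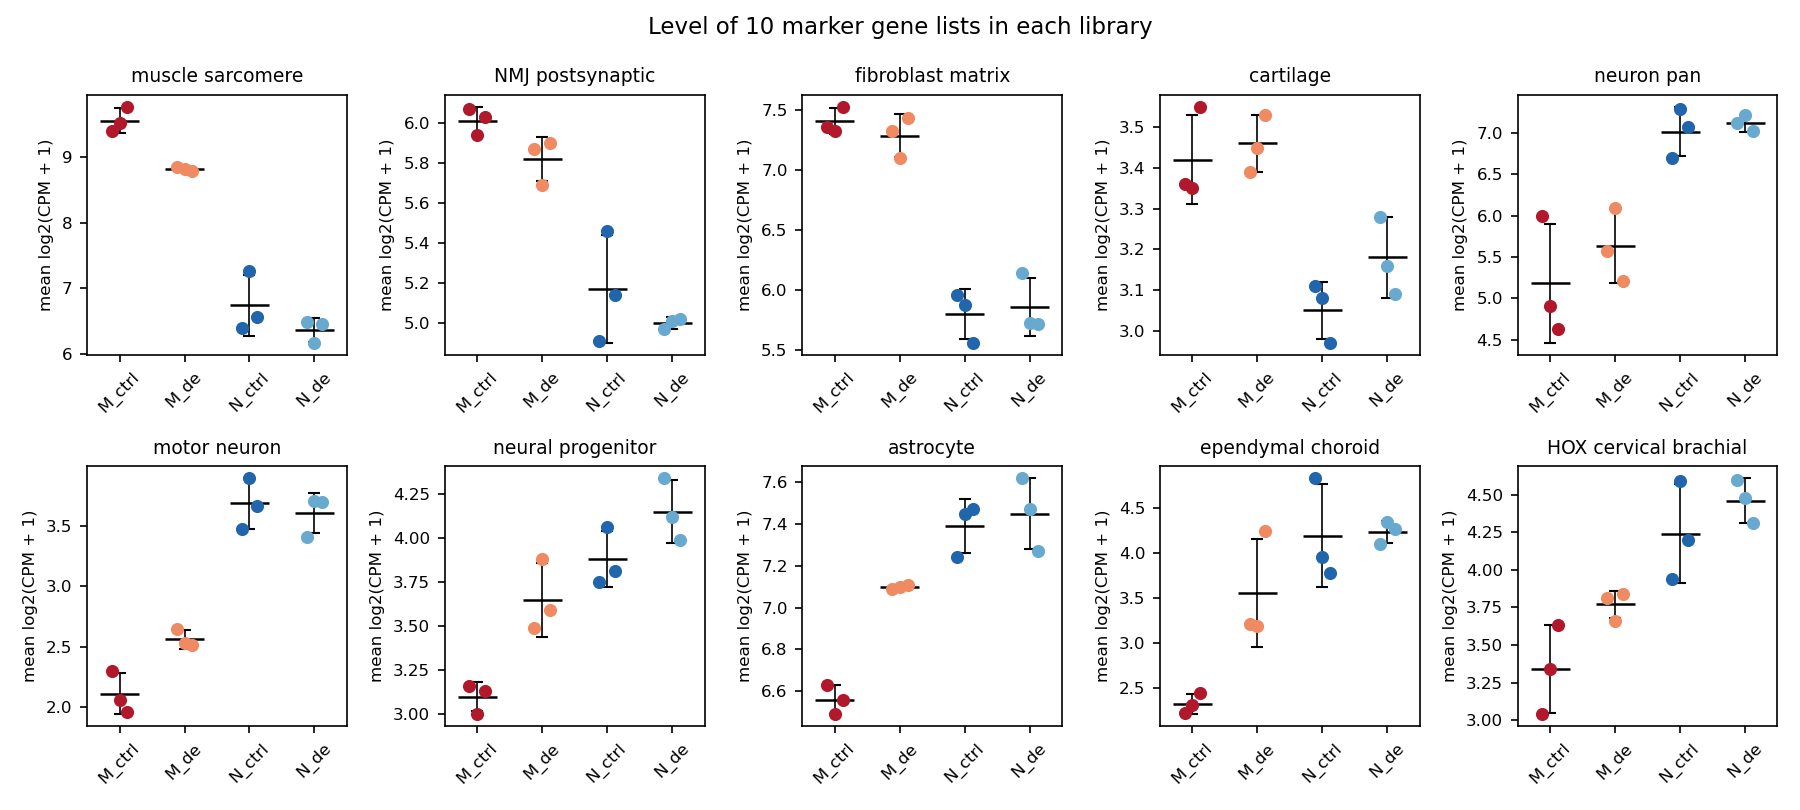
Level of 10 gene lists, as mean log2(CPM + 1) over the tested members, in the 12 libraries. Points are libraries, horizontal lines are group means and bars are SDs (n = 3); the sarcomere list averaged 9.55 in M_ctrl, 8.81 in M_de, 6.74 in N_ctrl and 6.37 in N_de, and the astrocyte list 6.56, 7.10, 7.39 and 7.45.

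In M_de relative to M_ctrl, 13 of 46 sarcomere genes were called lower, and 11 of 17 ciliated cell genes, 7 of 27 neural progenitor genes and 7 of 20 astrocyte genes were called higher. The 4 lists were called with the preset correlation and not with an estimated correlation, where their adjusted p was 0.224 to 0.245. This comparison asks how the libraries labelled de differed from those labelled ctrl under the prefix M. MYH7 went from 1300 ± 274 to 471 ± 55.7 CPM (SD, n = 3), a log2 fold change of -1.46 ± 0.27 (SE) with an adjusted p of 0.0118 in edgeR. SHH went from 8.46 ± 2.19 to 28.4 ± 2.27 CPM, a log2 fold change of 1.74 ± 0.20 with an adjusted p of 0.00313. GFAP, the intermediate filament gene of astrocytes, went from 851 ± 119 to 2030 ± 196 CPM, a log2 fold change of 1.26 ± 0.18 with an adjusted p of 0.0055. In total 651 genes were higher and 189 lower in M_de.

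Of 46 sarcomere genes 13 were called lower in M_de and none higher (28 lower adjusted over the list alone), and all 46 had a negative fold change. Their median log2 fold change was -0.73 with a camera adjusted p of 1.96e-25 (adjusted p = 0.245 with an estimated correlation). The giant sarcomere proteins TTN and NEB had log2 fold changes of -1.25 ± 0.22 and -1.20 ± 0.21, and MYOM1 and MYBPC1 had -1.13 ± 0.16 and -1 ± 0.15. Of 12 slow fibre genes 2 were lower (8 adjusted over the list alone), with a median of -0.74 and an adjusted p of 2.5e-08 (adjusted p = 0.297 with an estimated correlation). Of 14 fast fibre genes 3 were lower (8 adjusted over the list alone), with a median of -0.80 and an adjusted p of 4.79e-08 (adjusted p = 0.297 with an estimated correlation). Of 22 genes of excitation-contraction coupling 2 were lower (11 adjusted over the list alone), with a median of -0.67 and an adjusted p of 1.2e-10 (adjusted p = 0.297 with an estimated correlation). MYL2, the slow myosin light chain gene, had -1.88 ± 0.44 and ACTN3 had -1.16 ± 0.25. MYH8 stood at 8330 ± 314 and 4320 ± 341 CPM with an adjusted p of 0.0148, whereas MYH3 stood at 18200 ± 3600 and 10800 ± 284 CPM and was not called, with an adjusted p of 0.0826.

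Of the 24 myogenic regulators 1 was lower by either adjustment, with a median log2 fold change of -0.44 and a camera adjusted p of 2.72e-05 (adjusted p = 0.322 with an estimated correlation), and a median of -0.22 without M_ctrl replicate 3. Of 17 postsynaptic genes 3 were lower and 1 higher by either adjustment, with a median of -0.20 and an adjusted p of 0.0327 (adjusted p = 0.565 with an estimated correlation), a call that ended without M_ctrl replicate 1 or M_de replicate 2. CHRNA1 and CHRNG had -0.96 ± 0.20 and -0.89 ± 0.22. Of 22 denervation and atrophy genes 4 were lower and none higher (6 lower adjusted over the list alone), with a median of -0.33 and an adjusted p of 0.000515 (adjusted p = 0.245 with an estimated correlation). FBXO32, a ubiquitin ligase gene of muscle atrophy, had -0.68 ± 0.16.

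Of 17 ependymal and choroid genes 11 were higher in M_de (14 adjusted over the list alone), with a median log2 fold change of 1.82 and a camera adjusted p of 7.88e-15 (adjusted p = 0.245 with an estimated correlation). Their level was 3.21, 3.19 and 4.24 in M_de replicates 1, 2 and 3, and its difference from M_ctrl went from 1.23 to 0.88 without M_de replicate 3. RSPH1 stood at 3.76 ± 0.553 CPM in M_ctrl and 21.9 ± 11.6 CPM in M_de, a log2 fold change of 2.55 ± 0.39, and the ciliary genes ROPN1L, CFAP77 and PIFO had 2.64 ± 0.47, 2.57 ± 0.47 and 1.74 ± 0.31. Of 27 neural progenitor genes 7 were higher (12 adjusted over the list alone), with a median of 0.65 and an adjusted p of 4.61e-08 (adjusted p = 0.245 with an estimated correlation). SOX2, which maintains neural progenitors, had 1.16 ± 0.19 and FOXA2 had 2.31 ± 0.41, and CORIN had 3.03 ± 0.51. Of 20 astrocyte genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 0.50 and an adjusted p of 1.13e-07 (adjusted p = 0.224 with an estimated correlation). S100B, SOX9 and CLU had 1.13 ± 0.19, 1.05 ± 0.18 and 1.12 ± 0.20. The largest fold among the genes named was that of PCDHGA6 at 4.75 ± 0.92, which is uncertain because clustered protocadherin genes share exons, and its mean in M_de was 5.13 ± 5.53 CPM.

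Of 16 motor neuron genes 3 were higher (4 adjusted over the list alone), with a median log2 fold change of 0.56 and a camera adjusted p of 0.000367 (adjusted p = 0.297 with an estimated correlation). CHAT, SLC5A7 and RET had 1.71 ± 0.32, 1.39 ± 0.33 and 0.94 ± 0.22. Of 26 general neuronal genes 1, NEFL at 1.35 ± 0.26, was higher by either adjustment, with a list median of 0.36 and an adjusted p of 0.0122 (adjusted p = 0.647 with an estimated correlation). The M_ctrl libraries were not all below the M_de libraries, with levels of 6, 4.91 and 4.63 against 5.57, 6.10 and 5.21. The level difference of 0.45 was 0.86 without M_ctrl replicate 1, 0.17 without M_ctrl replicate 3 and 0.21 without M_de replicate 2. The list's call ended without M_ctrl replicate 2 or 3 or M_de replicate 2, with adjusted p values of 0.142, 0.519 and 0.46. The growth cone gene GAP43 was not called, at 1.14 ± 0.34 with an adjusted p of 0.0863. Of 23 cervical and brachial HOX genes 6 were higher (8 adjusted over the list alone), with a median of 0.47 and an adjusted p of 4.41e-05 (adjusted p = 0.549 with an estimated correlation), and HOXA6 and HOXB5 had 2.11 ± 0.32 and 1.14 ± 0.24.

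Skeletal, matrix and respiratory chain lists had smaller median fold changes than the sarcomere list. No tendon and ligament gene of 18 was called by edgeR over all genes, while 4 were lower when adjusted over the list alone, with a median log2 fold change of -0.47 and a camera adjusted p of 0.000213 (adjusted p = 0.297 with an estimated correlation). The tendon genes KERA and COL14A1 had -2.52 ± 0.69 and -0.65 ± 0.18, with adjusted p values of 0.058 and 0.0628. Cartilage genes were not called as a list, with 2 of 30 higher and 3 lower by either adjustment and a median of -0.09, and ACAN, the main cartilage proteoglycan gene, had -1.67 ± 0.37. Fibroblast matrix genes were not called either, with an adjusted p of 0.0671 and a median of -0.20. Of 50 nuclear respiratory chain genes 4 were lower (5 adjusted over the list alone), with a median of -0.31 and an adjusted p of 1.05e-05 (adjusted p = 0.629 with an estimated correlation), and SDHA had -0.77 ± 0.15. M_ctrl replicate 1 stood below every M_de library in this list, with M_ctrl levels of 6.67, 7.57 and 7.74 against 7.12, 7.19 and 7.05. The median was -0.55 without that library, -0.19 without M_ctrl replicate 2, and -0.10 without M_ctrl replicate 3, where the call ended with an adjusted p of 0.0837.

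In all, 20 lists were called with the preset correlation, 7 higher and 13 lower, and none with an estimated correlation, where the smallest adjusted p was 0.224. Fry called 3, the astrocyte, neural progenitor and denervation and atrophy lists, with adjusted p values of 0.00828, 0.0366 and 0.0458. The count of 840 genes dropped to 298 without M_ctrl replicate 2, 457 without M_de replicate 1 and 163 without M_de replicate 3. It was 551 at 2-fold or more, 1550 in DESeq2, 550 in limma voom, 1470 without a filter on low counts, and 74 with only the compared groups in the fit. After correction for length and GC content it was 2610, of which 1143 were higher and 1467 lower, so the excess of higher over lower calls turned. That correction also changed the scaling between libraries, and whether the turn came from this was not tested. Of the 44 named genes called here, 13 were called whichever library was left out: CORIN, FOXA2, GFAP, HOXA6, MYBPC1, MYOM1, NEB, ROPN1L, RSPH1, S100B, SHH, SOX2 and TTN.

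**Figure D2:**
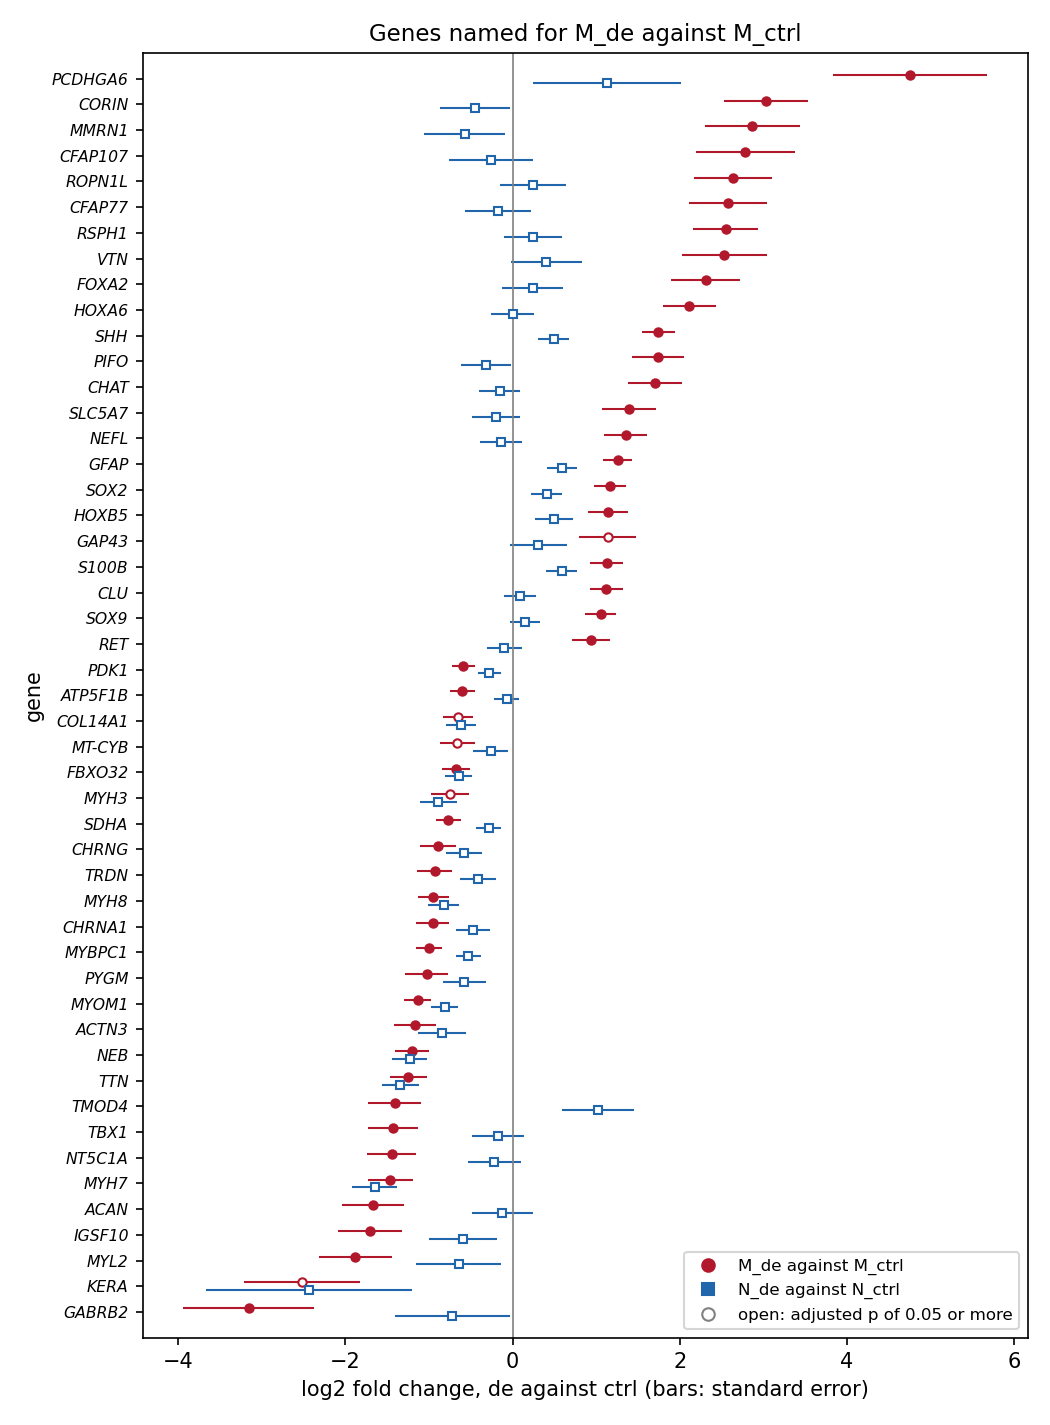
Log2 fold change of de against ctrl for 49 genes named for M_de against M_ctrl, under the prefix M (circles) and the prefix N (squares), with SE bars (n = 3 per group) and open symbols at an adjusted p of 0.05 or more. MYH7 had -1.46 under M and -1.65 under N, and RSPH1 had 2.55 under M, where its difference between the prefixes was not called (adjusted p 0.11).

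GPNMB, a glycoprotein gene of lysosomes and melanosomes, was the 1 coding gene called between N_de and N_ctrl. It stood at 42.4 ± 4.02 CPM in N_ctrl and 19.7 ± 2.25 CPM in N_de (SD, n = 3). Its log2 fold change was -1.11 ± 0.15 (SE) with an adjusted p of 0.0379 in edgeR. This comparison asks how the libraries labelled de differed from those labelled ctrl under the prefix N. The other gene called was ENSG00000271581, an unprocessed pseudogene that stood at 0.431 ± 0.203 CPM in N_ctrl and 6.9 ± 2.38 CPM in N_de, with a log2 fold change of 3.96 ± 0.52 and an adjusted p of 0.0379. It falls outside the naming rule and was chosen after its values were seen. It lies on chromosome 6 from 31356647 to 31357637 and overlaps HLA-B on the opposite strand, so its reads are uncertain; HLA-B stood at 116 ± 40.3 and 126 ± 6.89 CPM with an adjusted p of 0.869. These calls compare with 2720 genes at an unadjusted p under 0.05. GPNMB was also called without N_ctrl replicate 2, with an adjusted p of 0.0247, but without any other library its adjusted p was 0.0967 to 0.522.

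Of 46 sarcomere genes none was called in N_de against N_ctrl by edgeR over all genes, while 12 were lower when adjusted over the list alone and 38 had a negative fold change. Their median log2 fold change was -0.41 with a camera adjusted p of 1.93e-09 (adjusted p = 0.886 with an estimated correlation). TTN stood at 635 ± 58.8 and 250 ± 47.6 CPM, a log2 fold change of -1.35 ± 0.22 with an adjusted p of 0.139, and MYH7 and NEB had -1.65 ± 0.27 and -1.23 ± 0.21 with adjusted p values of 0.139 and 0.142. Slow fibre genes had a median of -0.50 and an adjusted p of 0.00082 (adjusted p = 0.886 with an estimated correlation), with 2 of 12 lower adjusted over the list alone. Myogenic regulators had a median of -0.32 and an adjusted p of 0.00343, and excitation-contraction coupling genes had -0.25 and 0.0213 (adjusted p = 0.886 for either with an estimated correlation), with 0 and 1 lower adjusted over the list alone. Before correction for length and GC content the coupling call ended without N_de replicate 2 (adjusted p 0.0777). After correction, with all libraries, the coupling genes had -0.40, with an adjusted p of 1.68e-05. Without N_ctrl replicate 2, the N_ctrl library with the highest sarcomere level at 7.26, the lists called numbered 5 and all were higher in N_de, so no muscle list was called lower. The sarcomere median then went to -0.11, as did the level difference, from -0.37, and the slow fibre and regulator medians to -0.22 and -0.06, while the coupling median turned to 0.19. With that library left out and the trend on length and GC content taken out, 9 lists were called, and the sarcomere, slow fibre, fast fibre and myogenic regulator lists were lower, with adjusted p values of 2.78e-08, 0.00964, 0.0163 and 0.02. The fast fibre list was not called before correction (adjusted p 0.101, and adjusted p 0.886 with an estimated correlation), and the coupling list was not called here (adjusted p 0.224).

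Lists higher in N_de included ribosomal protein genes, with a median log2 fold change of 0.44 and a camera adjusted p of 9.49e-07, and nuclear respiratory chain genes, with 0.36 and 6.49e-05 (adjusted p = 0.886 for either with an estimated correlation). After correction for length and GC content these medians were 0.23 and 0.17, with adjusted p values of 0.00714 and 0.00299. None of their members was called by edgeR, whether over all genes or adjusted over the list alone. Hypoxia and glycolysis genes had a median of 0.19 and an adjusted p of 0.00082 (adjusted p = 0.886 with an estimated correlation), with 6 of 34 higher adjusted over the list alone. VEGFA stood at 182 ± 39.6 and 362 ± 80.4 CPM, with an adjusted p of 0.17. Interferon genes had a median of 0.27 and an adjusted p of 0.00454, neural progenitor genes 0.34 and 0.00984, and cervical and brachial HOX genes 0.37 and 0.0103 (adjusted p = 0.886 for each with an estimated correlation), with 3, 1 and 0 higher adjusted over the list alone. Corrected medians were 0.12 for hypoxia and glycolysis, 0.10 for neural progenitor and 0.18 for HOX genes, with adjusted p values of 2.72e-05, 0.0286 and 0.0403. Cholesterol synthesis genes were lower as a list, with a median of -0.28 and an adjusted p of 0.0148 (adjusted p = 0.886 with an estimated correlation), and 3 of 23 were lower and 1 higher adjusted over the list alone, with a corrected median of -0.18 and adjusted p of 0.0004. The cholesterol call ended without N_ctrl replicate 2 (adjusted p 0.513, or 0.0564 when also corrected) and without N_de replicate 3 (adjusted p 0.0504). The interferon call ended without N_ctrl replicate 2 (adjusted p 0.337, or 0.328 when also corrected) and without N_de replicate 2, where the median was -0.01; the N_de levels were 4.06, 4.64 and 4.07 against 4.19, 3.88 and 3.9 in N_ctrl. The neural progenitor and HOX calls each ended without N_ctrl replicate 1 (adjusted p 0.052 and 0.196) or N_de replicate 1 (adjusted p 0.0878 and 0.0798). The ribosomal median was 0.23 without N_ctrl replicate 1 and 0.82 without N_ctrl replicate 2, the respiratory median 0.62 without N_ctrl replicate 2, and the hypoxia median 0.06, 0.35 and 0.08 without N_ctrl replicate 1, N_ctrl replicate 2 and N_de replicate 1.

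Fold changes of N_de against N_ctrl followed transcript length and GC content, with rank correlations of -0.34 and 0.51 across 15317 coding genes, which are not independent replicates; for M_de against M_ctrl they were 0.02 and 0.07. N_ctrl replicates 1, 2 and 3 had median log2 deviations of -0.95, -0.19 and -0.79 for transcripts of up to 1000 bases, and the N_de libraries had -0.12, -0.13 and -0.01. Called genes numbered 998 without N_ctrl replicate 2 and 0 without any 1 of the other 5 libraries. Corrected for length and GC content they numbered 21, and 77 when N_ctrl replicate 2 was also left out. DESeq2 called 250, no filter on low counts gave 235, only the compared groups gave 8, and limma voom and a minimum of 10 CPM gave 0. The 12 lists called compare with up to 22 in other splits of the same 6 libraries, and with 0 by an estimated correlation or by fry.

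**Figure D3:**
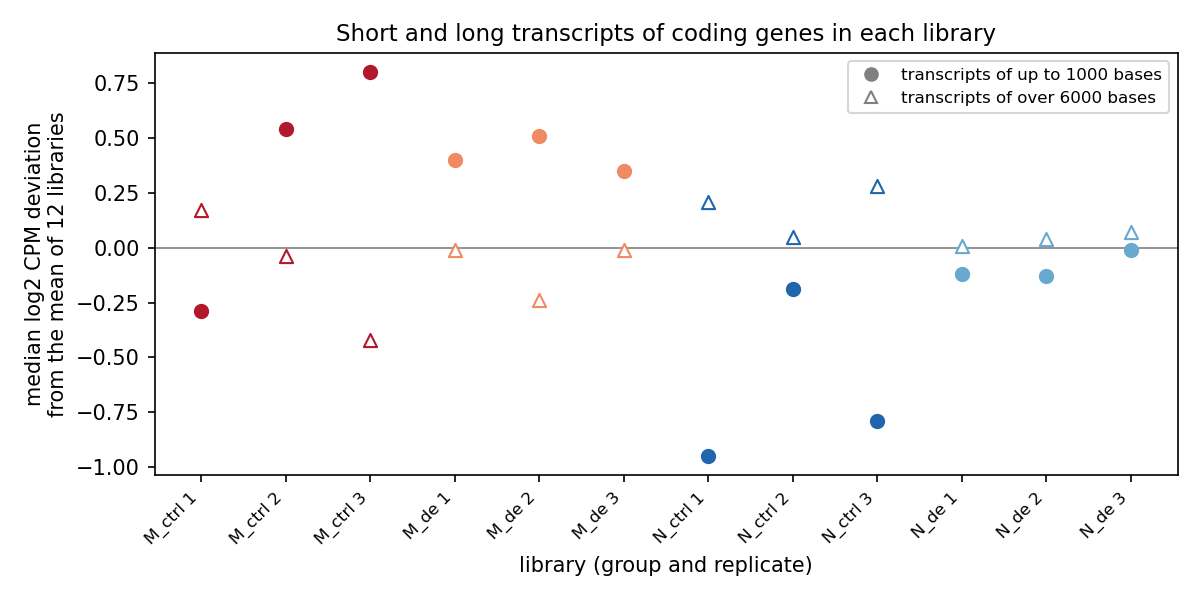
Median log2 CPM deviation from the mean of the 12 libraries for coding genes with transcripts of up to 1000 bases (filled circles) and over 6000 bases (open triangles), 1 pair per library, coloured by group. Short transcripts lay at -0.95 and -0.79 in N_ctrl replicates 1 and 3, at -0.29 in M_ctrl replicate 1, and at 0.35 to 0.80 in the other M libraries.

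The effect of de was called different between the prefixes M and N for 4 genes, all with a higher log2 fold change under M. NEDD9, a scaffold protein of cell adhesion, stood at 12.2 ± 1.2 CPM in M_ctrl and 31 ± 6.84 CPM in M_de but at 99.6 ± 12.1 and 65.7 ± 2.62 CPM in N_ctrl and N_de (SD, n = 3). The difference of its log2 fold changes was 1.95 ± 0.24 (SE) with an adjusted p of 0.0315 in edgeR. PCSK1, a prohormone-processing enzyme, had a difference of 1.97 ± 0.27 with an adjusted p of 0.0346, and stood at 7.14 ± 1.78 and 26.2 ± 2.49 CPM under M and at 135 ± 24.4 and 126 ± 11.4 CPM under N. RCAN3, a calcineurin regulator, had 1.75 ± 0.24 with an adjusted p of 0.0346, and GLRA2, a glycine receptor subunit, had 1.61 ± 0.23 with an adjusted p of 0.035. Genes at an unadjusted p under 0.05 numbered 2045.

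As lists, ependymal and choroid genes had a median difference of 1.91 and a camera adjusted p of 1.29e-13 (adjusted p = 0.59 with an estimated correlation), with none of 17 called by edgeR over all genes and 12 higher adjusted over the list alone. RSPH1 and PIFO had differences of 2.30 ± 0.51 and 2.05 ± 0.43 with adjusted p values of 0.11 and 0.0967. Motor neuron genes had a median of 0.81 and an adjusted p of 7.96e-05, with 4 of 16 higher adjusted over the list alone, and astrocyte genes had 0.48 and 4.65e-05, with 7 of 20 higher and 1 lower (adjusted p = 0.59 for either with an estimated correlation). Neural progenitor genes had a median of 0.50 and an adjusted p of 0.00658 (adjusted p = 0.641 with an estimated correlation), with 2 of 27 higher adjusted over the list alone, a call that ended without M_de replicate 2 (adjusted p 0.162) or N_ctrl replicate 2 (adjusted p 0.113). The motor neuron median was 0.53 without M_ctrl replicate 2. Sarcomere genes had a median of -0.32 and an adjusted p of 4.65e-05 (adjusted p = 0.641 with an estimated correlation), with none of 46 called by either adjustment, and MYBPC1 had -0.47 ± 0.21 with an adjusted p of 0.454. The sarcomere median was -0.18 without N_ctrl replicate 1 and -0.59 without N_ctrl replicate 2. Nuclear respiratory chain genes had a median of -0.65 and an adjusted p of 1.29e-13, with a negative difference in all 50 (adjusted p = 0.641 with an estimated correlation). Ribosomal protein genes had a median of -0.55 and an adjusted p of 1.25e-06, with a negative difference in all 46 (adjusted p = 0.78 with an estimated correlation), and after correction for length and GC content the median was -0.30 and the adjusted p 0.00466. The ribosomal median was -0.35 without M_ctrl replicate 3 or N_ctrl replicate 1 and -0.95 without N_ctrl replicate 2.

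The 13 lists called, 5 higher and 8 lower, became 21 without N_ctrl replicate 1 and 0 with an estimated correlation or by fry. The 4 genes became 273 without N_ctrl replicate 2, 69 without M_de replicate 2, 27 without M_ctrl replicate 1 and 1 without M_ctrl replicate 3, and 0 without any 1 of the other 8 libraries. They became 65 after correction for length and GC content, 453 in DESeq2 and 593 with no filter on low counts. With the replicate number or the table order as a block they became 0.

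GPNMB was the 1 gene called lower in both comparisons of de with ctrl, against 0.00978 for independent lists, and it stood at 175 ± 22.7 and 93.7 ± 5.4 CPM in M_ctrl and M_de. No gene was called higher in both by edgeR, against 0.0337, and none in opposite directions. Of the 189 genes lower in M_de, 166 had a fold change below 0 under N, where 51.6% of all genes did, and of the 651 genes higher in M_de, 357 lay above 0 under N. The fold changes of the comparisons, which share no library, had a Pearson correlation of 0.25 and a Spearman correlation of 0.28 across 15098 genes. The overlap was 80 genes in DESeq2, 13 after correction for length and GC content and 49 without N_ctrl replicate 2. It was 2 without M_de replicate 2, and 0 without N_ctrl replicate 1 or 3 or any N_de library.

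Positions are those of GENCODE release 29 on GRCh38. MYH7 (ENSG00000092054) lies on chromosome 14 from 23412738 to 23435718, and TTN (ENSG00000155657) on chromosome 2 from 178525989 to 178830802. SHH (ENSG00000164690) lies on chromosome 7 from 155799986 to 155812273, and GPNMB (ENSG00000136235) on the same chromosome from 23235967 to 23275108. RSPH1 (ENSG00000160188) lies on chromosome 21 from 42472486 to 42496354, and GFAP (ENSG00000131095) on chromosome 17 from 44903161 to 44916937. NEDD9 (ENSG00000111859) lies on chromosome 6 from 11183298 to 11382348, and PCSK1 (ENSG00000175426) on chromosome 5 from 96390415 to 96434143. RCAN3 (ENSG00000117602) lies on chromosome 1 from 24502351 to 24541040, and GLRA2 (ENSG00000101958) on chromosome X from 14529298 to 14731812. Each is annotated as protein coding.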

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

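The tests of mixing, muscle share, length and GC content and labels below were chosen after the results they bear on were seen, and the rule for mixing was rewritten to cover every share after narrower forms of it had been run; the counts over other splits of the libraries were planned.

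The effect of de differed between the prefixes M and N by the interaction test for 4 genes and, with the preset correlation, for 13 lists, of which 0 were called with an estimated correlation, where the smallest adjusted p was 0.59. The difference of log2 fold changes was 1.61 for GLRA2, 1.95 for NEDD9, 1.75 for RCAN3 and 1.97 for PCSK1. The median difference was 1.91 for ependymal and choroid genes, 0.81 for motor neuron genes, 0.50 for neural progenitor genes, 0.48 for astrocyte genes and 0.30 for cell cycle genes. It was -0.32 for sarcomere genes, -0.48 for fast fibre genes, -0.40 for excitation-contraction coupling genes and -0.30 for tendon and ligament genes. It was also -0.42 for hypoxia and glycolysis genes, -0.65 for nuclear respiratory chain genes, -0.47 for mitochondrially encoded genes and -0.55 for ribosomal protein genes. After correction for length and GC content it was -0.28 for the mitochondrially encoded genes, which were then not called (adjusted p 0.0563), -0.30 for the ribosomal protein genes, 0.14 for the cell cycle genes, -0.31 for the fast fibre genes and -0.49 for the tendon and ligament genes. With 1 library left out, the tendon and ligament call ended without M_ctrl replicate 1, 2 or 3, M_de replicate 2, N_ctrl replicate 2 or 3 or N_de replicate 1, the neural progenitor call without M_de replicate 2 or N_ctrl replicate 2, the fast fibre call without N_ctrl replicate 3 and the mitochondrial call without M_ctrl replicate 3. Chance was not excluded for either count. Of 100 splits drawn from 200, 6 gave at least 4 genes, with up to 243 in another split, and 58 gave at least 13 lists, with up to 25. The split with 243 genes kept the M groups as they are and joined N_ctrl replicate 1 with N_de replicates 2 and 3. It thus still holds the real difference of M_de from M_ctrl, where 840 genes were called, and that difference may give many of its calls. The real split holds the same difference and gave 4 genes, so the grouping of the N libraries bears on the count too. The count therefore cannot show whether the samples hold a structure other than the groups. Splits that keep the groups of 1 prefix hold a real difference, so these shares do not measure chance alone.

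The sarcomere, fibre type and excitation-contraction coupling lists were lower and the neural progenitor, astrocyte and ciliated cell lists higher in M_de than in M_ctrl with the preset correlation, but not with an estimated correlation (adjusted p 0.224 to 0.297). A share of N_ctrl-like tissue mixed in stays open: the muscle lists gave 49.7% (jackknife SE 4.57) and all 15098 genes 25.6% (SE 4.87), and 4 of 101 shares tried held both the sarcomere and the fibroblast matrix list within 2 SE, but every share left at least 2 of 15 lists over 2 SE away, the farthest by at least 3.99 SE. A smaller muscle share with all other tissues raised alike was argued against, since the ciliated and fibroblast matrix lists moved apart by 3.89 SE. Length and GC content did not account for it: 826 of the 840 genes called stayed called in the same direction after correction. The median absolute log2 fold change of the 840 was 1.22 (median SE 0.25) before. After correction it was 1.17 in the direction called before (median SE 0.22). An effect of de on the makeup or state of the tissue stays open as an untested hypothesis, as does a combined change in several tissues, since the labels do not define de.

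Far more genes, 998, were called in N_de against N_ctrl when N_ctrl replicate 2 was left out. Of these, 47 stayed called in the same direction once the trend on length and GC content was taken out. The median absolute log2 fold change of the 998 was 0.85 (median SE 0.19) before. After correction it was 0.39 in the direction called before (median SE 0.15). The genes were picked by their calls before correction, so part of the shrinking may come from that. The calls ended with smaller folds and not with larger SEs. This is consistent with a trend on length and GC content in N_ctrl replicates 1 and 3 as the source of most of them. A wrong label on N_ctrl replicate 2 cannot be told apart from a real spread: of 77 genes called from the other 5 libraries after correction, 34, or 44.2%, had that library nearer to the other N_ctrl libraries. A biological effect of de under N stays open and untested.

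Ribosomal protein and nuclear respiratory chain lists were higher in M_ctrl than in N_ctrl with the preset correlation, but not with an estimated correlation (adjusted p 0.302 for either). The length and GC content trend was argued against as the whole cause, since the ribosomal median was 1.91 before and 1.37 after correction, and the lowest M_ctrl library stood at 9.16 against 8.70 for the highest N_ctrl library. The respiratory median went from 1.64 to 1.19, with 6.82 against 6.32. Scaling to library totals instead of TMM left 1.47 of a ribosomal level difference of 1.8, and an error shared by all scalings was not tested. A difference in tissue between the prefixes may remain, and part of the difference did follow length and GC content.

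For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In M_de against M_ctrl the real split, the 1 of 10 with as many, called 840 genes, the highest other 0, and 20 lists, the highest other 17. In M_ctrl against N_ctrl it called 9296 genes, the highest other 106, and 28 lists, the highest other 22. In N_de against N_ctrl it called 2 genes, the highest other 0, and 12 lists, the highest other 22, with 7 splits giving at least 12 lists.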

How the results depend on the processing

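The correction for length and GC content, the same without N_ctrl replicate 2, and the block by table order were chosen after the data were seen; the other alternatives were planned. No named gene changed direction under any setting run. The 43 genes named for M_ctrl against N_ctrl were called whichever library was left out, and its 9296 calls changed by over 1.5 times at a 2-fold minimum alone, to 5778. Named genes were picked for large fold changes or small p with all libraries. That they kept their direction or call was thus likely in advance and says little about other genes. Over single left-out libraries, genes called ranged from 163 to 1107 in M_de against M_ctrl, 0 to 998 in N_de against N_ctrl, 7842 to 9909 in M_ctrl against N_ctrl and 0 to 273 in the interaction. Lists ranged over 19 to 26, 5 to 16, 26 to 29 and 11 to 21 in that order, and the overlap over 0 to 49. Of the comparisons of named genes with 1 library left out, 689 kept their side of the threshold, 136 lost a call and 27 gained it.

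In M_de against M_ctrl, DESeq2 called 1550 genes, limma voom 550, no filter 1470, only the compared groups 74, a 2-fold minimum 551, the corrected model 2610 and the table order block 475. The share of higher calls was 77.5% and became 43.8% with the correction, which also changed the scaling between libraries. In N_de against N_ctrl they called 250 (DESeq2), 0 (voom), 235 (no filter), 0 (10 CPM), 8 (only the compared groups), 21 (corrected), 77 (corrected without N_ctrl replicate 2) and 0 (table order), beside 2720 genes at an unadjusted p under 0.05 in edgeR. In the interaction they called 453 (DESeq2), 593 (no filter), 65 (corrected), 336 (corrected without N_ctrl replicate 2) and 0 (table order), beside 2045 at an unadjusted p under 0.05. With an estimated correlation, 0, 0 and 0 lists were called in these 3 comparisons and 1 in M_ctrl against N_ctrl. The overlap of 1 gene was 80 in DESeq2, 13 corrected and 0 at a 2-fold minimum. The cause was not tested for DESeq2, voom, the filter, the table order and the fit of only the compared groups. The latter left fewer libraries to estimate the spread. It lowered the calls in M_de against M_ctrl but raised those in N_de against N_ctrl from 2 to 8.

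No pairing by replicate number was seen: same-numbered pairs had correlations of -0.23 to 0.16 in their deviations from group means. Of the 18 pairs 1 was over 0.1, and 0 libraries correlated best with their own number. These deviations from means of 3 libraries also hold each library's trend on length and GC content. They cannot exclude that libraries with the same number shared a culture. With the replicate block, 511 genes were called in M_de against M_ctrl, 1 in N_de against N_ctrl and 0 in the interaction, and with the replicate block within each prefix 452, 0 and 0.

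Small level differences changed sign. For M_de against M_ctrl, fibroblast matrix genes gave 0.04 without TMM. Ribosomal protein genes gave -0.38 to 0.3 over left-out libraries, with -0.03 without M_de replicate 2 and -0.38 without M_ctrl replicate 1. For N_de against N_ctrl, neuronal genes gave -0.06 (without N_ctrl replicate 1) to 0.23, and ependymal genes -0.16 to 0.37, with -0.01 without N_de replicate 2, -0.08 without N_ctrl replicate 2 and -0.16 without N_ctrl replicate 3. Astrocyte genes gave -0.02 to 0.15, with -0.02 without N_de replicate 1 and -0.01 without N_ctrl replicate 1. Fibroblast matrix genes gave -0.08 to 0.14, with -0.08 without N_de replicate 1 and -0.06 without N_ctrl replicate 3. The cause was not tested. With 3 libraries a group, 36.6% of simulated 2-fold changes were called in M_de against M_ctrl and 9.86% in the interaction. Most simulated effects of that size were thus missed, and the share missed in the real data was not measured.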

Other observations

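The lists given here and the comparison of fold changes at the end were chosen after the results were seen. The endothelial list averaged 1.38 ± 0.02 in M_ctrl, 1.42 ± 0.08 in M_de, 1.09 ± 0.05 in N_ctrl and 1.14 ± 0.11 in N_de as mean log2(CPM + 1) (SD, n = 3). The macrophage list averaged 1.76 ± 0.22, 1.67 ± 0.15, 1.81 ± 0.17 and 1.80 ± 0.14 in the same order, and the pluripotency list 1.37 ± 0.19, 1.57 ± 0.17, 1.58 ± 0.13 and 1.53 ± 0.01. The surface epithelium list averaged 2.79 ± 0.11, 2.92 ± 0.09, 2.93 ± 0.06 and 2.81 ± 0.07. The levels cover tested members only: 10 of 18 endothelial, 6 of 17 macrophage, 5 of 12 pluripotency and 15 of 20 epithelium genes. In M_ctrl against N_ctrl 5 endothelial genes were called higher and 2 lower, and 5 epithelium genes higher and 6 lower. Fry gave these lists adjusted p values of 0.000939 and 0.0412 there, and the macrophage and pluripotency lists 0.1495 and 0.538. None of these 4 lists was called by camera in any of the 4 comparisons before correction for length and GC content. After it the surface epithelium list was called for the difference of the de effect between M and N, with an adjusted p of 0.0286 against 0.0657 before (adjusted p = 0.606 with an estimated correlation, before correction).

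Genes of heat shock were not called as a list in M_de against M_ctrl, and those of the unfolded protein response were called only after correction for length and GC content. The unfolded protein list had a median log2 fold change of 0.22 in M_de against M_ctrl, with a camera adjusted p of 0.0598 (0.17 and 0.034 after correction, and an adjusted p of 0.629 with an estimated correlation before it), and the heat shock list 0.10, with an adjusted p of 0.661. The Schwann cell and oligodendrocyte list was higher in M_de, with a median of 0.48 and an adjusted p of 0.025 (adjusted p = 0.529 with an estimated correlation; 0.221 without M_ctrl replicate 1), with 2 of 20 genes higher and 1 lower (4 and 1 adjusted over the list alone). Cell cycle genes had a median of 0.30 in M_ctrl against N_ctrl, with 10 of 36 called higher (8 adjusted over the list alone) and an adjusted p of 0.0428 (adjusted p = 0.42 with an estimated correlation), a call that ended without M_ctrl replicate 2 or 3 or N_ctrl replicate 2 or 3.

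The fold changes of M_de against M_ctrl ran against those of M_ctrl against N_ctrl, with a Pearson correlation of -0.73 across 15098 genes, which are not independent replicates. The M_ctrl libraries enter both, and 20 simulations of an unchanged M_de gave a mean of -0.12. The covariance was -0.307, against -0.0311 in the simulations. The simulations drew each gene independently, so they left out that genes vary together between real libraries. M_ctrl replicates 1, 2 and 3 lay at -68.6, -96.5 and -117.6 on the first principal component, which separated M from N. The simulated values may thus understate what the shared M_ctrl libraries alone can give, and they cannot set these aside. Of the 651 genes higher in M_de, 637 were also called lower in M_ctrl than in N_ctrl, where independent lists would share 159. Of the 189 genes lower in M_de, 175 were also called higher in M_ctrl than in N_ctrl, where independent lists would share 44.8. Independent lists leave out the shared controls, so the overlaps alone do not measure a reversal.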
